A study of Drosophila melanogaster with 6 samples.

How the data were processed

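The series holds poly(A)-selected RNA-seq libraries from the larval fat body of Drosophila melanogaster, the insect organ that stores fat and glycogen and secretes most blood proteins. There were 6 samples, 3 from females and 3 from males of the white-eyed laboratory stock w1118. Per the labels' protocols, larvae were reared at 25 °C and 60% humidity, 50 larvae to a vial, were sexed, and were dissected in the third instar. Per the same protocols, each sample pooled 50 fat bodies, RNA was extracted with TRIzol and column-purified with DNase I digestion, and 500 ng went into a mRNA-Seq library kit.

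The deposited files are salmon tables with 1 row per transcript. Per the series design text, reads were assigned by pseudo-alignment to FlyBase transcriptome dmel_r6.48_FB2022_05, and DESeq2 1.40.1 and gProfiler 0.2.1 were used downstream by the submitters. The salmon version, its options, the strand setting and any read trimming are not stated. The deposited estimated counts (expected reads per transcript) are not normalised. The deposited TPM values are scaled to a fixed total with salmon's effective lengths, per the file headers. The deposited transcript lengths and effective lengths are other quantities in bases.

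Of 29936 transcripts in the files, 29926 were matched by identifier to 13771 genes of the Ensembl annotation of assembly BDGP6 (release 115), from which all coordinates were taken. The 10 unmatched transcripts held at most 0.00274% of a library's reads. The transcripts are those of protein-coding genes, so the non-coding RNAs roX1 and roX2 were not analysed here. Estimated counts were summed per gene and rounded to whole numbers. Library totals ranged from 27907783 to 34906488 estimated reads. A gene with 0 reads in all 3 female libraries was given a floor of 3 counts over the group, which is 0.0357 CPM. Reads carry no molecular identifiers in the files, so floors cover counting error only. Reads shared between near-identical copies, between overlapping genes and between isoforms of 1 gene were divided by salmon's model, and such values are uncertain.

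Males were compared with females with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, and the quasi-likelihood test with Benjamini-Hochberg adjustment over the 10872 genes tested, at an adjusted p of 0.05. Log2 ratios are male over female, and their standard errors are the ratio divided by the square root of the F statistic. CPM values are TMM-scaled unless stated. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, repeated with an estimated correlation, and with fry. Isoform usage was tested with edgeR's diffSpliceDGE and a Simes adjustment per gene. For the X chromosome, each library's median deviation from the gene means over X-linked genes was taken relative to that over autosomal genes, for genes with a mean of at least 1 CPM. Sums of marker genes and X values were compared with exact permutation tests, 2-sided, for which 3 against 3 libraries allow no p under 0.1.

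The 48 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 8 genes per direction with the largest log2 ratio among called genes with at least 5 CPM in the higher sex and no overlap between the sexes. It also took the 8 per direction with the smallest p among called genes with a log2 ratio of at least 0.58 and at least 10 CPM in each sex. A fixed set was always named: Sxl, tra, dsx, msl-2, fru, roX1, roX2, spen, nito, Yp1, Yp2, Yp3, Lsp1alpha and bmm. From each list described, the 2 to 4 members with the smallest p could be named, and non-passing members with their values. Other genes named are said to be chosen later.

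Alternatives included DESeq2 1.42.0, DESeq2's size factors, TMM on autosomal genes, no filter, length offsets, limma on log2(TPM + 1), a replicate block and the omission of each library. After the data were seen, a second scaling was added because many genes were found almost solely in male libraries. This female-expressed scaling computes TMM on the genes with a female mean of at least 10 CPM. Those 4398 genes were also fitted alone. Selecting them on their female level leaves out genes that are low in females, and can favour genes that are high in females by chance. The second scaling raises male to female log2 ratios by a median of 0.228.

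The steps were tested on simulated data drawn from the libraries' own means and dispersions, with 3 against 3 libraries. For males against females over 10748 genes, 98% of 100 genes changed 4-fold and 29% of 100 genes changed 2-fold were recovered, and 8 unchanged genes were called. Camera called the 1 planted list and 0 of 20 unchanged random lists. Genes were drawn independently there, so false calls from correlation between genes could not appear. In the data the estimated correlation within a list reached 0.798 (glycogen and trehalose). For isoform usage over 4194 genes, diffSpliceDGE recovered 81% of 100 genes with a transcript changed 16-fold and 20% of 100 changed 4-fold, and 12 of its 113 calls were unchanged genes. When genes under 10 CPM in females were simulated at their male means and the other 4398 were left equal, TMM over all tested genes gave these 4398 a median log2 ratio of -0.15 and called 90 of them higher in females and 9 higher in males. The female-expressed scaling gave a median of 0.005, with 28 and 22 such calls. When only genes under 1 CPM in females were simulated at their male means, the medians were -0.064 and 0.012, with 36 and 21 calls by the first scaling and 21 and 30 by the second.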

Results

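RNA from the fat body of third-instar larvae was sequenced in 3 libraries from females and 3 from males, each a pool of 50 fat bodies. The total was 27907783, 34906488 and 31512138 estimated reads in the female libraries and 30735406, 33154694 and 29454344 in the male libraries. At least 10 reads were found for 8742 to 8975 genes per female library and for 10764 to 11165 genes per male library. The storage protein gene Lsp1beta took the most reads of any gene in each library, 9.98% to 11.5%, without correction for transcript length. The comparison of the sexes addresses sex differences in samples of a fat-storing tissue, which also held transcripts of other tissues.

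Males differed from females mainly through genes that were almost absent from the female libraries. Of 10872 genes tested, 3046 were higher in males and 729 higher in females, and 2712 of these differed at least 2-fold (edgeR quasi-likelihood test, adjusted p under 0.05, n = 3 per sex). Of the 3046 genes higher in males, 2190, or 71.9%, had under 1 CPM in females. Genes under 1 CPM in females took 0.0601% ± 0.0064 (SD, n = 3) of female reads and 1.96% ± 0.75 of male reads. Testis tissue in the male libraries is a possible source of such genes, as examined below. With scaling on female-expressed genes, chosen after the data were seen, the split became 3469 higher in males and 207 higher in females. Omission of 1 library moved the female-higher count to as few as 239 (without female 1), with 391 without female 3 or without male 1 and 470 without male 3.

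The 8 genes with the largest male to female ratios had 0 reads in the female libraries, and several are known from sperm or testis. S-Lap7 (FBgn0033868, 2R, 13778124 to 13780245), S-Lap4 and S-Lap3, sperm leucyl aminopeptidases, had 109 ± 32.2, 92.3 ± 27.2 and 81.5 ± 27.8 CPM in males (SD, n = 3), at least 3051-fold, 2585-fold and 2281-fold above the female floor of 3 counts over the group. The others were loopin-1, CG12699, fest, CG15109 and CG33340, at 65.2 to 107 CPM in males and at least 1824-fold above the floor. Their adjusted p ranged from 8.38e-06 to 1.91e-05 in edgeR's test. All 57 tested members of the fixed spermatocyte list were higher in males, also when adjusted over the list alone. Among them Mst77F, a sperm chromatin protein gene, had 0.03 ± 0.04 CPM in females and 80.4 ± 16.2 in males, and dj (don juan), a sperm tail gene, 0.01 ± 0.02 and 29.6 ± 4.62. Summed CPM of that list was 33.6 ± 3.5 in females and 1602 ± 414 in males, with 2021, 1193 and 1592 in male libraries 1, 2 and 3 (exact permutation p = 0.1, the smallest possible, n = 3 per sex). Of the other germline lists, 18 of 19 testis-specific mitochondrial paralogs, 14 of 18 early germline genes and 8 of 8 Y-linked fertility genes were higher in males, with the same counts adjusted over the list alone.

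**Figure D1:**
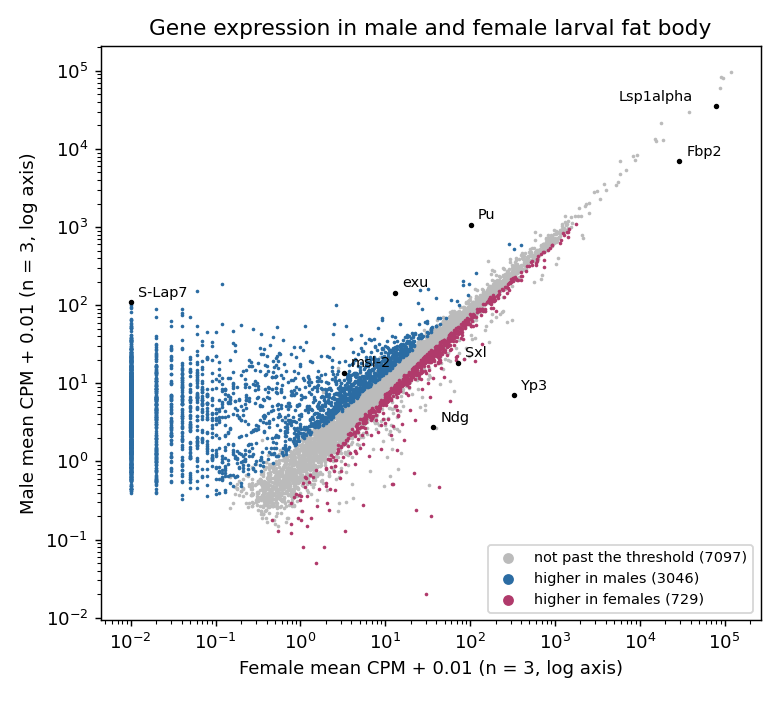
Mean CPM of each tested gene in males (vertical, log axis) against females (horizontal, log axis), n = 3 libraries per sex, with 0.01 CPM added; colours give the 3046 genes higher in males, the 729 higher in females and the 7097 not past the threshold. Most male-higher genes lie at the left edge, under 1 CPM in females, while Yp3, Ndg, Sxl and Fbp2 lie below the diagonal.

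Lists of ribosomal, proteasome and cell-cycle genes also held members higher in males, at no larger a share than the 3046 of all 10872 tested genes. In the list of cytosolic ribosomal proteins, 7 of 91 tested members were higher in males, among them RpL22-like (0.03 ± 0.03 CPM in females, 27.7 ± 3.85 in males) and RpS19b (0.50 ± 0.04 and 21.1 ± 2.41), and 12 were higher in females. Adjusted over the list alone these counts were 7 and 1, and with the female-expressed scaling 7 and 2. Of the 83 with at least 10 CPM in females, 0 passed when such genes were fitted alone. Of 38 proteasome genes 5 were higher in males and 0 in females, also when adjusted over the list alone, led by the variants Rpt4R (0.01 ± 0.02 and 16.2 ± 1.48 CPM) and Rpt3R (0.24 ± 0.09 and 16.7 ± 2.24). Again 0 passed of the 33 with at least 10 CPM in females when such genes were fitted alone. Of 30 genes of DNA replication and the cell cycle 8 were higher in males and 2 in females, with the same counts adjusted over the list alone, and 9 and 0 with the female-expressed scaling. Of the 5 with at least 10 CPM in females, 0 passed when such genes were fitted alone. The genes higher in males included the mitotic kinases aurA (0.83 ± 0.18 and 8.16 ± 2.07 CPM) and polo (9.09 ± 0.49 and 27.9 ± 5.33). The sum of the spermatocyte list was also higher in males, as given above. Whether these groups follow that sum from library to library was not tested for each group. Male-higher genes under 1 CPM in females were examined together, as described below.

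Among genes with at least 10 CPM in both sexes, the smallest p in the male direction went to exu, an RNA-localisation gene (FBgn0000615, 2R, 20667427 to 20671083), with 13.0 ± 1.68 CPM in females and 144 ± 47.5 in males. Its log2 ratio was 3.47 (SE 0.27, edgeR adjusted p = 1.87e-05). Pu (Punch, GTP cyclohydrolase I, the first enzyme of pteridine synthesis; FBgn0003162, 2R, 21175315 to 21182608) had 102 ± 21.6 CPM in females and 1075 ± 321 in males, a log2 ratio of 3.40 (SE 0.28, edgeR adjusted p = 2.39e-05). CG44774 rose from 25.8 ± 0.75 to 158 ± 48.0 CPM. The remaining 5, cnn, Nop17l, tra2, vih and CG4502, were 2.12-fold to 3.33-fold higher in males. The genes exu, Pu, cnn, Nop17l, tra2 and vih each overlap another annotated gene, with which reads could be shared. Male libraries 1, 2 and 3 had 193, 98.5 and 140 CPM of exu and 213, 123 and 137 CPM of CG44774. For Pu they had 836, 951 and 1439 CPM. The spermatocyte sum was likewise highest in library 1 and lowest in library 2, as for exu and CG44774 but not for Pu.

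Genes higher in females included yolk protein genes, the splicing regulator Sxl and a storage-type protein gene. Yp3 (FBgn0004047, X, 13759546 to 13761547), a yolk protein, had 326 ± 61.9 CPM in females and 7 ± 1.80 in males, a log2 ratio of -5.54 (SE 0.27, edgeR adjusted p = 6.12e-06). Yp2 had 3.36 ± 1.04 and 0.12 ± 0.07 CPM, and Yp1, too low to be tested, had 27 reads in the 3 female and 1 read in the 3 male libraries. Ndg (nidogen, a basement membrane protein; FBgn0026403, 2R, 10313891 to 10322104) had 36.8 ± 4.04 CPM in females and 2.71 ± 0.48 in males, a log2 ratio of -3.76 (SE 0.19, edgeR adjusted p = 6.12e-06). CG7290 had 43.6 ± 8.36 and 0.46 ± 0.76 CPM. The other genes with the largest ratios, CG32762, CG4151, CG10472, CG16749 and Eig71Ea, were uneven among females: CG32762 had 86.4, 2.94 and 0.66 CPM in female libraries 1, 2 and 3. Without female 1, the calls of CG10472 (edgeR adjusted p = 0.0704; range over alternatives 0.00187 to 0.0704) and CG16749 (0.0937; range 0.0104 to 0.0937) were lost, and each was lost in 3 other alternatives. CG32762 lost its call without male 1 and with limma (range of adjusted p 0.000326 to 0.0679). In edgeR's fit of genes with at least 10 CPM in females alone, CG32762 (adjusted p = 0.0729), CG4151 (0.0675), CG10472 (0.139) and Eig71Ea (0.0793) did not pass.

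By smallest p among genes of at least 10 CPM in both sexes, Sxl led the female direction, and the genes after it included CG42847, dob (a lipase-family gene), CG15347, CG6067, NdufV3 (a subunit of mitochondrial complex I) and Ctr1B (a copper transporter). These 6 were 1.93-fold to 2.82-fold higher in females. CG42847 overlaps the abundant Fbp2, with which it could share reads. Sxl and these 6 genes stayed higher in females under both scalings, and CG6067 lost its call with limma on log2(TPM + 1) (adjusted p = 0.0515).

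When the 4398 genes with at least 10 CPM in females were fitted alone, 159 were higher in males and 37 higher in females (edgeR, adjusted p under 0.05; 997 had an unadjusted p under 0.05). Of the 37, 36 were also called higher in females over all genes, and of the 159, 146 were called higher in males. X-linked genes made up 17 of the 37, or 45.9%, against 16.7% of the other genes (Fisher's exact test, 2-sided, odds ratio 4.23, 95% interval 2.07 to 8.56, p = 3.61e-05, across genes, which are not independent). Among the 159 male-higher genes, which are part of those other genes, 7 were X-linked, against 17% of all 4398. The number of calls varied with the library left out: 5 genes were called without female 1, 8 without female 2, 83 without female 3, 67 without male 1, 222 without male 2 and 13 without male 3. In each omission all 37 female-higher genes and 149 to 159 of the 159 male-higher genes kept their direction, which their selection from all 6 libraries favours. With at least 20 CPM in females the count was 23, and with at least 50 CPM it was 10.

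Transcripts of the sex-determination cascade differed between the sexes in the direction known for each sex, though not in an all-or-none way for Sxl and dsx. Sxl (Sex-lethal, FBgn0264270, X, 7074550 to 7098053), whose protein is made from its full reading frame in females, had 72.7 ± 5.36 CPM in females and 18.4 ± 2.28 in males, a log2 ratio of -1.98 (SE 0.15, edgeR adjusted p = 1.67e-05). Its 7 annotated transcripts with a short reading frame of 126 to 144 coding bases, ending at position 7088698, took 37.3% ± 0.73 of its reads in females and 78.8% ± 8.87 in males (SD, n = 3). The transcript tra-RA, with the long frame of transformer (591 coding bases), took 77.7% ± 14.1 of tra reads in females and 0 of 142 reads in males, which allows a share of up to 2.11%. For dsx (doublesex), the transcripts ending at the stop codon at 7930230 took 10.04% ± 1.27 in females and 88.1% ± 4.84 in males. Those ending at 7935562 took 90.0% ± 1.27 and 11.9% ± 4.84. The transcript msl-2-RB held 0 of 277 reads of msl-2 in females and 65.9% of the reads in males. Each of these shares separated the sexes without overlap (exact permutation p = 0.1, the smallest possible, n = 3 per sex; chance separates 10% of such comparisons). In diffSpliceDGE the adjusted p was 2.83e-08 for Sxl, 3.20e-07 for dsx, 0.000124 for msl-2 and 0.000653 for tra. For fru (fruitless) it was 1.00. Salmon's assignment among similar isoforms limits these shares.

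**Figure D2:**
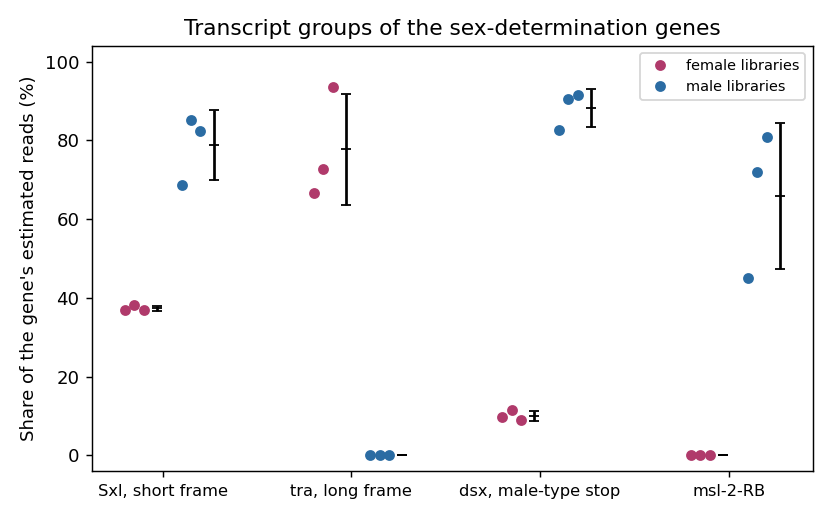
Share of each gene's estimated reads (vertical axis, %) taken by the short-frame transcripts of Sxl, the long-frame transcript of tra, the dsx transcripts with the stop codon at 7930230 (the male-type stop) and msl-2-RB, for each female and male library; black marks give the mean and SD of 3 libraries. No share overlaps between the sexes.

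Of 19 tested genes of sex determination, 1 was higher in males and 5 in females (2 and 6 adjusted over the list alone), and 2 and 2 with the female-expressed scaling. Total tra had 2.80 ± 0.01 CPM in females and 1.34 ± 0.13 in males, a log2 ratio of -1.06 (edgeR adjusted p = 0.00439; range over alternatives 0.000835 to 0.0739, the call being lost with scaling on genes of at least 50 CPM in females). For dsx the values were 16.8 ± 3.51 and 9.77 ± 1.13 CPM, with adjusted p = 0.0128 in edgeR and 0.0903 with the female-expressed scaling, which ends the call (range over alternatives 0.0041 to 0.242). The cofactor tra2 was higher in males, with 10 ± 0.50 and 25.2 ± 3.41 CPM. The RNA-binding proteins spen (95.1 ± 51.0 and 77.6 ± 11.4 CPM, edgeR adjusted p = 0.542) and nito, Spenito (19.7 ± 2.08 and 17.0 ± 1.18, adjusted p = 0.275), and fru (16.4 ± 5.84 and 11.99 ± 2.63, adjusted p = 0.254) did not pass. Of 6 genes of the dosage compensation complex, which acts on the male X, 4 were higher in males and 0 in females, also when adjusted over the list alone. They were msl-2 (3.25 ± 0.53 and 13.6 ± 1.57 CPM, log2 ratio 2.06), msl-3 (3.15 ± 0.32 and 8.82 ± 1.16), mof (3.61 ± 0.30 and 7.29 ± 0.34) and mle (13.1 ± 1.55 and 21.7 ± 2.44). In edgeR's fit of genes with at least 10 CPM in females alone, 1 of the 3 members present passed, mle (adjusted p = 0.0345). The spermatocyte sum was also higher in the male libraries, as given above. Male libraries 1, 2 and 3 had 24.4, 19.9 and 20.7 CPM of mle and 11.9, 13.7 and 15.1 CPM of msl-2. The value of msl-1 was 13.6 ± 3.14 and 13.1 ± 1.37 CPM (edgeR adjusted p = 0.871).

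Isoform usage differed in 381 of 4462 genes tested (diffSpliceDGE, adjusted p under 0.05), 238 of them among the 2862 tested genes with at least 10 CPM in females. With transcripts of at least 10 CPM alone the count was 34. Male libraries also held more spermatocyte transcripts, as given above, and their part in these isoform calls was not tested.

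Storage protein genes showed 1 female-higher member of 6 over all genes and over the list alone, and 2 with the female-expressed scaling. Fbp2 had 29376 ± 4287 CPM in females and 7019 ± 1225 in males, a log2 ratio of -2.07 (SE 0.33, edgeR adjusted p = 0.00117). Lsp1alpha, the X-linked subunit of larval serum protein 1, had 80210 ± 2872 and 35050 ± 7443 CPM, with adjusted p = 0.0535 in edgeR and 0.0147 with the female-expressed scaling (range over alternatives 8.31e-11 to 0.246). Lsp1beta had 117572 ± 4349 and 96520 ± 19281 CPM and Lsp2 96236 ± 4398 and 81221 ± 15532, and neither passed.

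Many metabolic lists had medians under 0 in males over all genes, and the number of member genes called depended on scaling, which moves all genes alike. Genes with at least 10 CPM in females had a median log2 ratio of -0.232, and -0.006 with the female-expressed scaling. For lipid storage and triglyceride synthesis, 4 of 18 members were higher in females and 0 in males (2 and 0 adjusted over the list alone), and 1 with the female-expressed scaling, Lsd-2, perilipin 2 (836 ± 125 CPM in females, 511 ± 48.5 in males, log2 ratio -0.71, or -0.49 with that scaling, adjusted p = 0.0155 and 0.0413 in edgeR). Lsd-2 did not pass over the list alone with that scaling, nor in edgeR's fit of genes with at least 10 CPM in females alone (adjusted p = 0.119), where 0 of 14 members passed. In lipolysis, 0 of 15 were higher in females and 1 in males, also over the list alone. The triglyceride lipase bmm (brummer) had 74.0 ± 10.5 and 61.9 ± 6.42 CPM (edgeR adjusted p = 0.240). In fatty acid synthesis 7 of 18 were higher in females and 1 in males (8 and 2 adjusted over the list alone), and 2 each with the female-expressed scaling. Baldspot, a fatty acid elongase, had 68.1 ± 7.88 and 34.7 ± 4.05 CPM, while the elongase bond had 0.62 ± 0.07 and 11.8 ± 2.49. In beta-oxidation 7 of 30 were higher in females and 0 in males, with 0 adjusted over the list alone and 0 with the female-expressed scaling. In glycolysis 4 of 13 were higher in females and 1 in males, also over the list alone, and 3 and 1 with the female-expressed scaling. PyK, pyruvate kinase, had 210.4 ± 9.23 and 133 ± 12.3 CPM and Pglym78, phosphoglycerate mutase, 171 ± 18.2 and 106 ± 11.1, while Pfk, phosphofructokinase, was higher in males (34.5 ± 1.5 and 48.7 ± 5.30). In edgeR's fit of genes with at least 10 CPM in females alone, 0 of 11 glycolysis members were higher in females (adjusted p = 0.0666 for PyK and 0.0646 for Pglym78) and 1 in males, Pfk (0.0489). For bond and Pfk, the spermatocyte sum was also higher in the male libraries, as given above. With CPM scaled on genes of at least 10 CPM in females, Pfk had 61.8, 43.3 and 54 CPM in male libraries 1, 2 and 3.

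Camera called 29 of 47 lists, 4 higher and 25 lower in males. With an estimated correlation it called 0, the smallest adjusted p being 0.520. The spermatocyte list, with all 57 tested members higher in males, also had 0.520 in that version. Its lack of calls thus does not argue against a list. Among genes with at least 10 CPM in females camera called 10 of 41 lists, 0 with an estimated correlation (adjusted p = 0.868 or more). In that set the median log2 ratio was -0.345 for ribosomal proteins, -0.183 for oxidative phosphorylation and -0.186 for beta-oxidation.

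**Figure D3:**
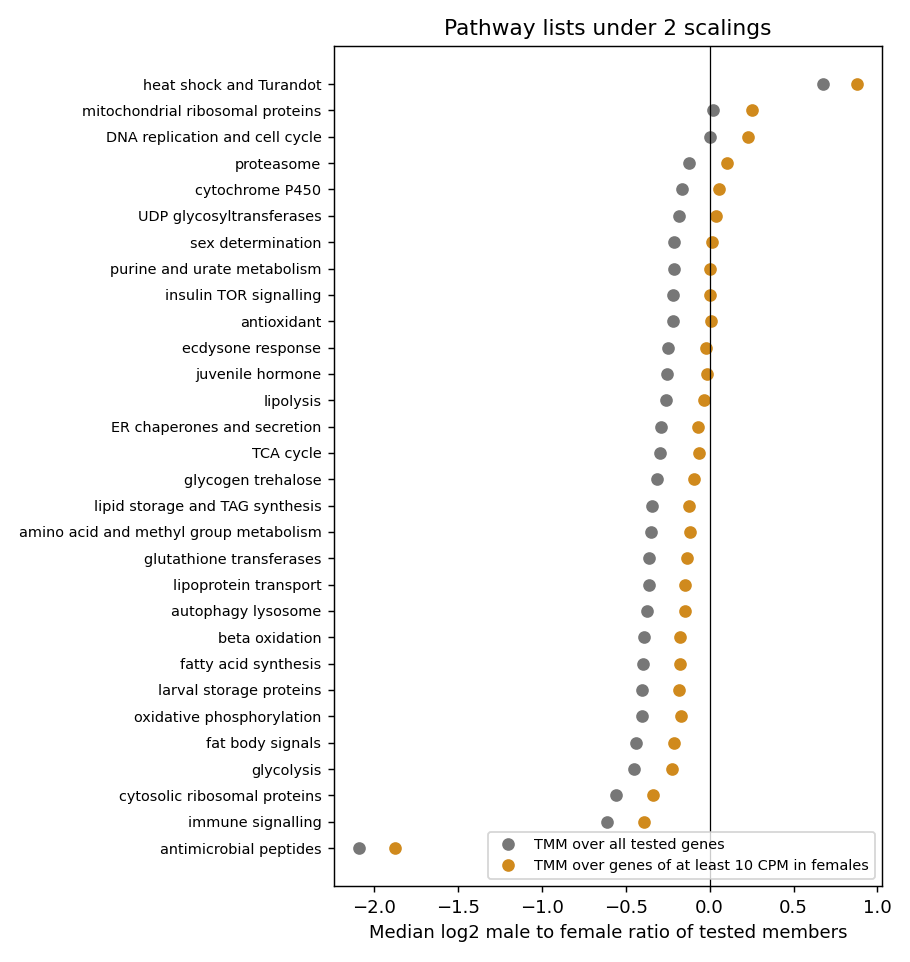
Median log2 male to female ratio of the tested members of each pathway list (horizontal axis) with TMM over all tested genes (grey) and over genes of at least 10 CPM in females (orange). The second scaling moves the medians right by about 0.228; beta-oxidation moves from -0.392 to -0.174.

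Immune genes were higher in females where they differed, but few were called among genes with at least 10 CPM in females fitted alone. In that fit 1 of 22 immune signalling genes, SPE (edgeR adjusted p = 0.0308), 0 of 17 antimicrobial peptide genes and 0 of 12 hemocyte genes passed. Of 24 genes of immune signalling, 10 were higher in females and 0 in males (13 and 0 adjusted over the list alone), and 4 with the female-expressed scaling. SPE, the Spätzle-processing protease, had 53.7 ± 6.21 CPM in females and 23.1 ± 5.67 in males, and the complement-like Tep1 60.2 ± 15.8 and 27.7 ± 2.27. Of 22 antimicrobial peptide genes, 6 were higher in females and 0 in males, with 0 adjusted over the list alone and 2 with the female-expressed scaling. CecC had 33.5 ± 28.5 and 6.69 ± 2.07 CPM, while Drs had 195 ± 83.4 and 187 ± 67.3. Of 14 hemocyte (blood cell) genes, 8 were higher in females and 0 in males (10 and 0 adjusted over the list alone), and 2 with the female-expressed scaling, Ppn (103 ± 13.5 and 54.0 ± 5.41 CPM) and NimC1 (15.8 ± 3.01 and 9.11 ± 0.80). With that scaling neither passed over the list alone, and in edgeR's fit of genes with at least 10 CPM in females alone the adjusted p was 0.0695 for Ppn and 0.103 for NimC1. The sum of the hemocyte genes was 1081 ± 63.7 CPM in females and 709 ± 29.2 in males (exact permutation p = 0.1, n = 3 per sex). Camera did not call these 3 lists with an estimated correlation (adjusted p = 0.520), as was so for the spermatocyte list. With TMM over all tested genes, fry called the hemocyte list (adjusted p = 0.00906). It did not call immune signalling (0.0999) or antimicrobial peptides (0.286).

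Of 19 heat shock and Turandot genes, 5 were higher in males and 0 in females (4 and 0 adjusted over the list alone), and 6 with the female-expressed scaling. DnaJ-1, a heat shock co-chaperone, had 59.2 ± 15.2 CPM in females and 116 ± 19.9 in males, Hsp68 39.8 ± 19.6 and 122 ± 40.0, and Hsp83 401 ± 33.8 and 585 ± 32.6. In edgeR's fit of genes with at least 10 CPM in females alone, 2 of 13 members passed, DnaJ-1 (adjusted p = 0.0308) and Hsp83 (0.0262). The spermatocyte sum, given above, was also higher in the male libraries. Hsp23 (615 ± 204 and 496 ± 282 CPM) and TotA (1031 ± 459 and 878 ± 185) did not pass.

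Transcripts of other tissues were present in both sexes. Salivary gland genes, chiefly glue protein genes, took 4.55% to 8.12% of reads per library, and their sum was 67552 ± 10540 CPM in females and 67600 ± 12538 in males (exact permutation p = 1). The digestive genes of the midgut summed to 7622 ± 3337 and 2662 ± 2822 CPM (p = 0.3, exact), with 5767, 5624 and 11474 in the female libraries and 5919, 947 and 1121 in the male libraries. The sums for muscle were 660 ± 113 and 659 ± 170 (exact p = 1). Sums of the gonad soma list were 432 ± 19.3 and 308 ± 37.3 CPM (exact p = 0.1). After adjustment over the 15 lists no exact p was under 0.25.

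**Figure D4:**
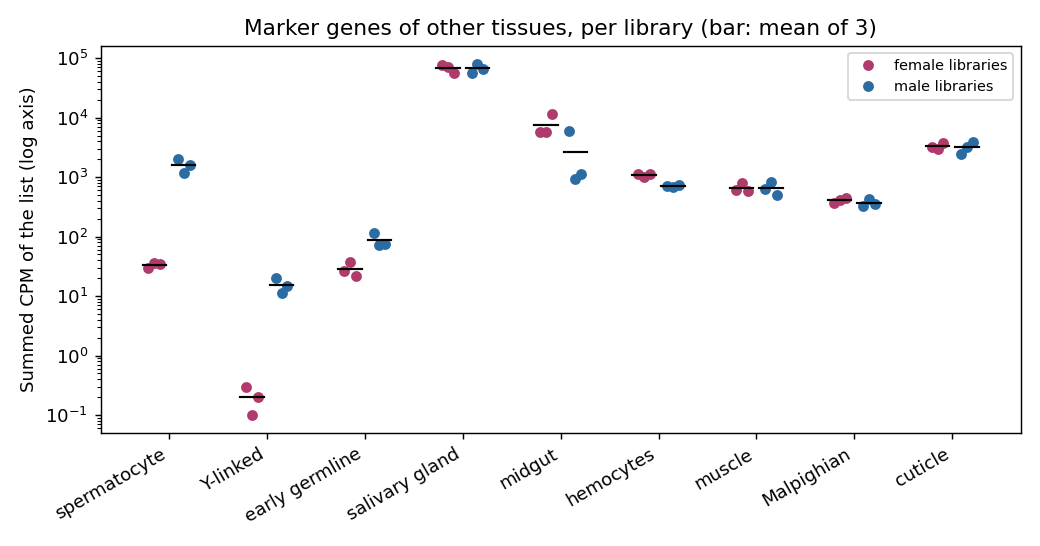
Summed CPM of marker genes of other tissues (vertical log axis) in each female and male library; bars give the mean of 3. Spermatocyte sums lie at 1193 to 2021 in males against a female mean of 33.6, and salivary gland sums overlap between the sexes.

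X-linked genes lay lower in males relative to autosomal genes. Over 1553 X-linked and 7922 autosomal genes, outside the testis, germline and Y-linked lists, the library value was 0.0836 ± 0.0431 in females and -0.0854 ± 0.0139 in males (log2, SD, n = 3). The difference was -0.169, or 0.889-fold, with no overlap between the sexes (exact permutation p = 0.1, the smallest possible). Camera on the X-linked genes gave p = 0.0392, and p = 0.0774 with an estimated correlation. Among genes with at least 10 CPM in females the difference was -0.157, and with at least 50 CPM it was -0.0890, both without overlap between the sexes.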

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

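The alternatives among genes of at least 10 CPM in females and the female-expressed scaling were chosen after the data were seen. The total of 3775 differing genes, the 3046 higher in males and the 2712 that differed at least 2-fold ranged from 2898 to 4170, from 2785 to 3750 and from 2127 to 2995 in the alternatives. The 729 genes higher in females fell to 113 with limma on log2(TPM + 1), to 207 with the female-expressed scaling and to 113 when that scaling used genes of at least 50 CPM; omission of 1 library gave 239 to 708. Of the differing genes, 80.7% were higher in males, against 96.1%, 94.4% and 97.1% in those alternatives.

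Among genes over 10 CPM in females, 196 differed (159 higher in males, 37 in females). The numbers became 23, 14 and 9 at 20 CPM, 10, 5 and 5 at 50 CPM, 500, 401 and 99 at 5 CPM, and 512, 332 and 180 with DESeq2. Omission of 1 library gave 5 to 222, 2 to 179 and 3 to 43. The cause of these shifts was not tested.

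The X difference of -0.169 ranged from -0.188 to -0.141 in the alternatives chosen before the data were examined and was -0.0890 at 50 CPM. Camera called 29 lists, 0 with an estimated correlation, 7 with fry, 10 among genes over 10 CPM in females and 0 there with an estimated correlation. Isoform calls went from 381 to 34 with transcripts of at least 10 CPM.

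The replicate numbers are shared between the sexes but the labels do not say that they mark a pairing. Deviations of same-numbered libraries correlated at 0.078, 0.053 and 0.068, each the best match for its number, a hint from the data. A replicate block gave 3442 genes, 31 lists and 258 isoform genes, and 55 genes (40 higher in males, 15 in females) over 10 CPM in females.

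For named genes, 626 alternative values kept the side of the threshold, 16 lost the call and 8 gained it. Genes called in the main fit kept their sign. The signs of fru, spen, nito and bmm, which were not called, changed in some alternatives (fru -0.651 to 0.00971). For lists, 438 values kept the side of the threshold, 103 lost the call and 11 gained it. The direction of some lists turned where they were not called. The proteasome list was lower in males over all genes and higher among genes over 10 CPM in females, uncalled in both. Depth limits genes under about 1 CPM.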

Other observations

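The tests on testis tissue, on scaling and on X-linked genes were chosen after the results were seen. The other splits of the libraries were chosen before the data were examined, except for the genes over 10 CPM in females, a set chosen after. Beyond the lists described, 4 of 10 oenocyte genes were higher in males, led by salm (1.21 and 4.24 CPM), and of 17 gonad soma genes 5 were higher in males and 2 in females, also adjusted over the list alone (5 and 1 with the female-expressed scaling). Six4 had 0.01 ± 0.02 CPM in females and 0.99 ± 0.06 in males, and bab2 9.43 ± 4.18 and 3.53 ± 0.56. Of 10 juvenile hormone genes, 2 were higher in each sex, also adjusted over the list alone, but 2 in males and 0 in females with the female-expressed scaling: Jhedup, a juvenile hormone esterase duplication, had 15.0 ± 6.09 CPM in females and 30.9 ± 2.97 in males, and the receptor gene gce 32.6 ± 8.17 and 19.1 ± 1.18.

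Genes nearly absent from females and higher in males may come from testis tissue in the male libraries, since the larval testis lies within the fat body. If so, they should follow the spermatocyte list from library to library. The 2100 such genes off the lists had a median log2 ratio of male library 1 to 2 of 0.838, near the 0.773 of the spermatocyte list and far from the 0.026 of female-expressed genes that were not higher in males. For the 159 genes over 10 CPM in females and higher in males, the median log2 ratio of the male excess over the female mean was 0.839. This too was nearer to the spermatocyte list. Subtracting the female mean enlarges small library differences, as in Utx, chosen later. It had 29.3 and 24.4 CPM in male libraries 1 and 2 and a log2 ratio of the excess of 0.976. The 0.026 is a ratio of total CPM, so 0.839 is not like for like with it and does not decide. Both 0.838 and 0.839 are medians. With CPM scaled on genes of at least 10 CPM in females, the excess was larger in library 2 in 10 of the 159. Among them were DnaJ-1, Had1 and ng2 (named after the data were seen). With that scaling Pu was highest in library 3 (1516 CPM, against 990 in library 1 and 966 in library 2). With TMM over all tested genes Pu had 836, 951 and 1439 CPM in libraries 1, 2 and 3, so the count of 10 depends on scaling. A fat body difference stays open for such genes. So does a share from other tissues in the libraries, such as salivary gland, which was not tested for them. A sex difference of the fat body itself was not separately tested.

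Metabolic and biosynthetic lists lower in males might reflect scaling and background set by genes found only in males. Of 12 such lists, 9 were called lower over all genes, and 4 stayed called lower among genes over 10 CPM in females, but this fit changed the scaling and the genes compared with at once. The calls that remained were lost with an estimated correlation. Over all genes that version did not call the spermatocyte list either, so it does not decide. The effects of scaling and of the gene set were not separated, and a sex difference in metabolism stays among the open explanations.

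X-linked genes lower in males could come from X-poor testis transcripts in the male libraries. The difference should then vanish among genes over 50 CPM in females, to which testis adds little. It was -0.0890, against -0.157 over 10 CPM and -0.169 over all genes, so it was smaller but not near 0 and the test does not decide. Male library 1, with the highest spermatocyte sum, had a value of -0.0899, close to the -0.0965 of library 2. Incomplete dosage compensation in the fat body stays open and was not tested.

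Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. As many genes as the real 3775 were called in 1 split, the real one, and the highest other split gave 0. The same held for the 2712 genes of at least 2-fold (1 split, highest other 0), the 381 isoform genes (1 split, highest other 5) and the 196 genes over 10 CPM in females (1 split, highest other 1). Every other split puts libraries of both sexes in each group, so the sex difference adds to the spread within groups. The low gene and isoform counts in those splits therefore say little about chance. For gene lists 2 splits called as many as the real 29, and the highest other called 33: female 1 with male 1 and male 2 against the rest. Camera with the preset correlation thus called many lists whatever the grouping, from 11 lists upward, and its calls do not set the sexes apart from other groupings.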
